A study of Mus musculus with 18 samples.

How the data were processed

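RNA was sequenced from 18 libraries, each made from 500 sorted cells with the SMART-Seq v4 kit and a modified Nextera XT protocol. The cells were CD4+ T cells of 3 littermate mice (84, 86 and 87) that carry an Id3-GFP and a Foxp3-mRFP reporter. Each mouse gave 3 sorted regulatory T cell (TR) populations from spleen and from peripheral lymph node. The labels name them central TR with the Id3 reporter (Id3+ cTR) and effector TR with it (Id3+ eTR) or without it (Id3- eTR). This makes 6 groups of 3 libraries from separate mice. Gene p-values measure variation between mice within groups, pooled over groups. List p-values set listed genes against others.

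The count table deposited by the authors holds whole-number counts per gene for 37991 genes, with no normalization. A second table by the authors, of normalized signal for 14011 genes, was matched to the counts by symbol for 13883 genes. There, 99.982% of the values equalled the count times 1 factor per library within 0.1%. All results below come from the counts. The submitters' processing notes name Bowtie, TopHat, HTSeq 0.4.1, FastQC, Picard and SAMtools. The genome build is not given in the sources used here, so no positions are printed. Gene symbols came from the GENCODE M21 annotation for 32919 of the gene identifiers, and the 5072 without a symbol held 0.891% of all counts.

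Library totals ran from 1600782 to 3153325 counts, with 13701 to 15045 genes detected. Genes with enough counts were kept with filterByExpr (minimum count 10), which left 12445 genes. Libraries were scaled by TMM, and 1 model with the 6 groups as its terms and 12 residual degrees of freedom was fitted to all 18 libraries by edgeR 4.0.16 (robust quasi-likelihood, two-sided F test) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The biological coefficient of variation was 0.294 and the median standard error of a log2 fold change was 0.316. CPM values use the TMM-scaled totals, and log2 CPM a prior count of 2. In data simulated at the observed spread, with 200 of the 12445 genes changed, the spleen contrast of Id3- eTR with Id3+ cTR called 38% of the genes changed by 2-fold and 65% of those changed by 4-fold, with 2 false calls among 105. The interaction contrast called 14% and 41%. With nothing changed, 0 genes were called.

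The contrasts were the 3 pairs of populations within each tissue, lymph node against spleen within each population, and 3 interactions (whether a population difference differs between the tissues). Gene lists were tested with camera on limma-voom values (limma 3.58.1, preset correlation 0.01) and Benjamini-Hochberg over 22 lists. These cover core TR genes, central and recirculating T cell genes, effector TR, tissue TR, homing receptors, E and Id proteins, follicular TR, T cell receptor-induced genes, suppressive function, helper lineage, TNF receptors and NF-kB, proliferation, glycolysis, sterol and lipid synthesis, interferon response, cytokine receptors and STAT5 targets, and dissociation stress. Markers of other cells were listed for B cells, myeloid and dendritic cells, CD8 T and NK cells, erythroid cells and platelets, and conventional CD4 T cells. A stromal and endothelial list had 1 tested gene and so no list test, and the 5 genes of the sort were not tested as a list. Several lists share genes: Klrg1, Il10 and Ctla4 each stand in more than 1, and Ifng and Il4 stand in the helper and the conventional CD4 lists. Every list was also tested with the correlation estimated from the data.

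Where a group had 0 counts of a gene, the fold is a lower bound that sets 3 counts over the whole group in its place. With 1 to 3 counts over the group, the ratio of CPM is given with its 95% counting interval. Such bounds and intervals cover counting error only. The step share places Id3+ eTR between Id3+ cTR and Id3- eTR. It takes genes called and changed at least 2-fold in 1 tissue, and in the other tissue divides their median log2 difference between Id3+ eTR and Id3+ cTR by that between Id3- eTR and Id3+ cTR, mouse by mouse.

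The contrasts, tests, lists, alternatives and a rule for the genes named were fixed before the data were examined, except where the text says otherwise. The rule named the sort genes and the E and Id proteins. From each list it took up to 2 members called in both tissues with the largest mean change, filled from 1 tissue where needed. Outside the lists it took the 5 highest and 5 lowest genes called in both tissues in the same direction in all mice with a mean log2 CPM of at least 3, then 5 each way between the tissues and up to 5 per interaction. It left out predicted genes and receptor segments. It named 106 genes, each refitted with single libraries left out. Some other genes named beside small counts, and genes said to be chosen after their values were seen, fall outside the rule and were not refitted library by library.

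Alternatives were RLE size factors, no filter on low counts, mouse as a block, DESeq2 1.42.0, limma-voom with sample weights, a fit of the groups compared alone, and leaving out each library in turn. The labels tie the 6 libraries of each mouse together. As a check of that tie, residual profiles of 45 pairs of libraries from the same mouse correlated at a median of 0.0188, and 14 of 18 libraries correlated best with their own mouse. Chosen after seeing the data were a fit without 337 genes that average over 0.3 counts per exon base, and a fit without 3 libraries that stand apart. These 3 are spleen Id3+ cTR of mice 84 and 87, with the lowest totals, and spleen Id3+ eTR of mouse 84, far from its group in the principal component plot. Spleen Id3+ cTR then keeps 1 library, which is assumed to vary like the other groups. Figures and summary tables used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Some results for single genes are not reported here.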

Results

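The 18 libraries of 500 sorted TR each form 6 groups of 3 mice (84, 86 and 87). Id3+ cTR were gated as CD44-low and Id3+ eTR as CD44-high, and the label of Id3- eTR states no such gate. In spleen, total counts per library ran from 1600782 to 2498377 in Id3+ cTR, 2439228 to 3153325 in Id3+ eTR and 2164402 to 2853467 in Id3- eTR. In lymph node they ran from 2593085 to 2988373, 2111016 to 2824045 and 2574681 to 2815399 in the same order. The lowest totals were those of spleen Id3+ cTR from mice 84 (1600782) and 87 (1684461). The spleen Id3+ cTR group also had the highest mitochondrial share, 0.552% ± 0.115 (SD, n = 3), against 0.391% ± 0.0897 in spleen Id3+ eTR. Spleen Id3+ eTR of mouse 84 differed most from its group, at 21.2 and 21.4 times the counting variance against its partners, where no other pair of a group passed 7.91. The series title speaks of a stepwise differentiation of TR defined by Id3, and the comparisons ask what separates each population from the next, in each tissue. A step below is a difference between sorted populations, as the libraries hold no time points or lineage tracing. Changes are log2 fold changes ± SE with 3 libraries per group, and each call given here with its log2 change or fold for a gene of the naming rule went the same way in 3 of 3 mice. Other genes are named beside small counts or were chosen after their values were seen. Calls and their absence are those of edgeR with all 18 libraries unless another tool or fit is named.

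The transcripts of the sort markers followed the gates. Id3, which encodes an inhibitor of E proteins, stood at 278 ± 26.5 CPM (SD, n = 3) in spleen Id3+ cTR, 248 ± 38.4 in Id3+ eTR and 58.5 ± 12.5 in Id3- eTR. In lymph node Id3 stood at 269 ± 22.0, 296 ± 7.65 and 71.4 ± 11.3. Cd44 stepped up from 59.5 ± 4.36 through 137 ± 25.9 to 212 ± 27.6 CPM in spleen. Foxp3, which encodes the lineage factor of TR, gave no call in any population comparison, with log2 changes from -0.10 ± 0.14 to 0.14 ± 0.14. Cd4 gave none either, with log2 changes from -0.11 ± 0.16 to 0.24 ± 0.16. Since the cells were sorted on these proteins and reporters, these genes are not independent evidence of a difference.

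**Figure D1:**
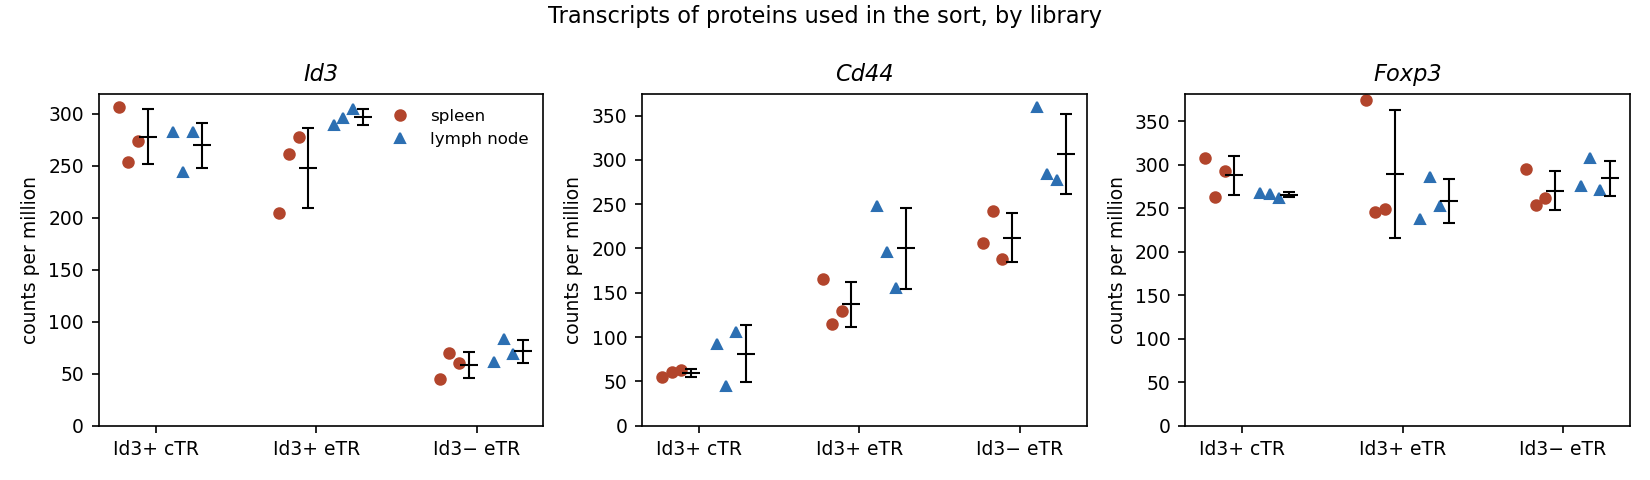
Expression of Id3, Cd44 and Foxp3 (vertical axis, CPM) in each population of spleen and lymph node; points are libraries and the dash with bar is the mean ± SD of 3 mice. In spleen mean Id3 is 278 CPM in Id3+ cTR, 248 in Id3+ eTR and 58.5 in Id3- eTR, while mean Cd44 rises at each step.

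Among all genes, the first principal component (31.6% of the variance) ordered the populations. In spleen it placed Id3+ cTR at -57.9 ± 1.32 (SD, n = 3), Id3+ eTR at -4.73 ± 5.97 and Id3- eTR at 49.9 ± 5.52. In lymph node it placed them at -56.4 ± 3.53, 12.4 ± 3.04 and 56.7 ± 3.19. The second (8.97%) set Id3+ eTR apart from both others, at 33.6 ± 21.8 in spleen and 30.4 ± 3.89 in lymph node, where the other 4 groups lay between -22.2 and -11.3. The wide spread in spleen comes from Id3+ eTR of mouse 84, at 58.6.

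**Figure D2:**
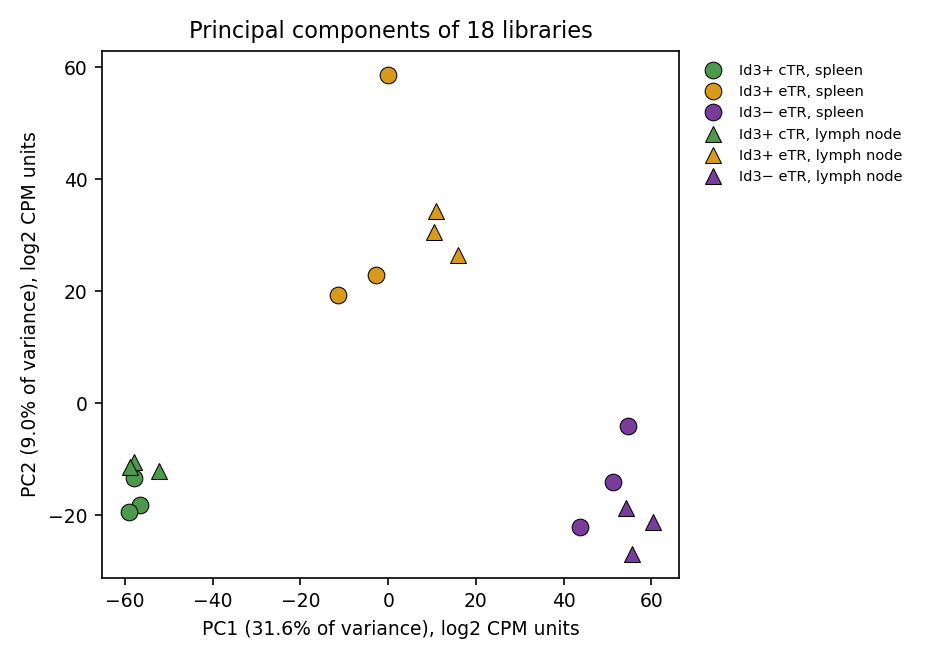
First and second principal components of log2 CPM (scores, with the share of variance on each axis); each point is a library, coloured by population and shaped by tissue. Id3- eTR lie at 49.9 and 56.7 on average on the first component and Id3+ cTR at -57.9 and -56.4, with Id3+ eTR between them and apart on the second.

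Id3- eTR against Id3+ cTR spans the whole path. In Id3- eTR the genes of effector and tissue-seeking TR were higher and those of recirculating T cells lower, in both tissues. Ccr2, a chemokine receptor that draws cells to inflamed tissue, was higher by 8.69 ± 0.41 on the log2 scale in spleen (adjusted p = 9.06e-10). In lymph node, where Id3+ cTR had 2 counts, the ratio was 1900-fold (95% interval 527 to 15700). Klrg1, a receptor of terminally differentiated lymphocytes, was higher by 7.86 ± 0.52 in spleen (adjusted p = 2.98e-08) and 878-fold (243 to 7260) in lymph node. Il10, an anti-inflammatory cytokine, was higher by 7.87 ± 0.89 in spleen (adjusted p = 1.23e-05) and 8.56 ± 0.86 in lymph node (adjusted p = 2.8e-06). Igfbp4, a gene of naive T cells, was lower, at -6.32 ± 0.51 (adjusted p = 3.29e-07) and -6.96 ± 0.51 (adjusted p = 1.04e-07).

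The fit called 1526 genes in spleen (892 higher and 634 lower in Id3- eTR) and 1610 in lymph node (1028 and 582). Of these, 633 were higher and 311 lower in both tissues, where independent calls would give 73.7 and 29.7, and 1 gene was called in opposite directions: Itga4, described with the tissues. Without the 3 libraries that stand apart the spleen count was 730, of which 661 were among the 1526.

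Id2, the other Id protein with a clear level here, moved against Id3: it was higher by 2.02 ± 0.15 in spleen (adjusted p = 1.67e-07) and 1.78 ± 0.15 in lymph node (adjusted p = 4.43e-07). Id3 itself was at -2.25 ± 0.16 and -1.91 ± 0.16 (adjusted p = 7.05e-08 and 3.44e-07). None of the E protein genes Tcf3, Tcf4 and Tcf12, nor Id1, was called. Their log2 changes were 0.33 ± 0.39, -1.10 ± 0.83, -0.30 ± 0.20 and -1.36 ± 1.20 in spleen, and -0.42 ± 0.38, 0.92 ± 0.78, -0.23 ± 0.20 and 0.67 ± 1.03 in lymph node. The E and Id list as a whole was not called (adjusted p = 0.597 and 0.956).

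Of 24 effector TR genes, 21 were higher in spleen and 22 in lymph node, and none lower (adjusted over the list alone 23 and 24; list adjusted p = 2.07e-05 and 1.16e-05 with an estimated correlation). Tissue TR genes were higher for 15 of 20 in each tissue and lower for none (18 and 19 adjusted over the list alone; adjusted p = 0.000103 and 4.41e-05 with an estimated correlation). They include Il9r, a receptor of a mast cell and TR cytokine, at least 46.8-fold higher in spleen and 610-fold (109 to 24200) in lymph node. Homing receptors were higher for 16 of 23 in spleen and 17 in lymph node, with Selplg lower in spleen and Itga4 in lymph node. The counts were 17 higher and 1 lower, and 17 and 3, adjusted over the list alone (adjusted p = 2.07e-05 and 4.41e-05 with an estimated correlation). Central and recirculating genes were lower for 18 of 20 in spleen, and in lymph node for 16, with only Il7r higher. Adjusted over the list alone 19 and 18 were lower and 1 and 1 higher (adjusted p = 2.07e-05 and 6.74e-05 with an estimated correlation). Among these, Dapl1 was at -6.03 ± 0.80 (adjusted p = 7.04e-05) and -5.25 ± 0.75 (adjusted p = 0.000122).

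Suppressive function genes were higher for 11 of 15 in spleen and 12 in lymph node, none lower (12 and 0, and 13 and 1, adjusted over the list alone; adjusted p = 9.4e-05 and 3.85e-05 with an estimated correlation). Havcr2, which encodes the inhibitory receptor TIM-3, was 91-fold (16 to 3620) higher in spleen and at least 148-fold in lymph node. Helper lineage genes were higher for 10 of 12 in each tissue, as many as adjusted over the list alone, with adjusted p = 0.000128 and 0.000353 with an estimated correlation. Il4, the type 2 cytokine, was at least 30.3-fold higher in spleen and 37.1-fold in lymph node. Il23r, a receptor of the type 17 lineage, was higher by at least 41.5-fold and 87.8-fold (adjusted p = 0.133 in spleen without the 3 libraries that stand apart). Core TR genes went both ways in spleen, 7 of 16 higher and 3 lower (8 and 3 adjusted over the list alone), and the list call was lost there (adjusted p = 0.0909 with an estimated correlation). In lymph node 9 were higher and Gpr83 alone lower (10 and 2 adjusted over the list alone; adjusted p = 0.0089 with an estimated correlation). Gpr83, a neuropeptide receptor of TR, was at -1.88 ± 0.18 and -1.79 ± 0.18 (adjusted p = 2.11e-06 and 2.4e-06). Nt5e, which encodes the adenosine-forming enzyme CD73, was at 1.35 ± 0.18 and 1.91 ± 0.18 (adjusted p = 5.75e-05 and 1.16e-06).

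The T cell receptor-induced list gave 7 of 16 higher and Myc lower in spleen, and 5 higher and Myc lower in lymph node (10 and 2, and 8 and 1, adjusted over the list alone). Its call was lost (adjusted p = 0.0754 and 0.0914 with an estimated correlation). Pdcd1, which encodes PD-1, was higher by 2.96 ± 0.32 and 2.82 ± 0.32 (adjusted p = 8.53e-06 and 1.06e-05), while Myc, a growth regulator, fell from 187 ± 32.7 to 93.2 ± 15.8 CPM (SD) in spleen and from 271 ± 22.3 to 66.9 ± 7.55 in lymph node (adjusted p = 0.000278 and 2.32e-07). Follicular TR genes were higher for 6 of 14 in spleen, with Btla and Tnfsf8 lower (7 and 2 adjusted over the list alone; adjusted p = 0.0881 with an estimated correlation). They were higher for 7 in lymph node with Tnfsf8 lower (9 and 1; adjusted p = 0.0107 with an estimated correlation). Angptl2, a secreted glycoprotein, was at least 93.4-fold higher in spleen and 456-fold (126 to 3770) in lymph node. TNF receptor and NF-kB genes were higher for 5 of 17 in spleen and 6 in lymph node (10 and 1, and 6 and 0, adjusted over the list alone; adjusted p = 0.0623 and 0.0796 with an estimated correlation). Among them Tnfrsf1b was at 2.15 ± 0.42 and 2.19 ± 0.40 (adjusted p = 0.00203 and 0.00114). Of 24 cytokine receptor and STAT5 genes, 9 were higher and 3 (Il2ra, Il6ra and Il6st) lower in spleen, and 10 higher in lymph node. Adjusted over the list alone it was 11 and 3, and 10 and 1 (adjusted p = 0.0909 and 0.03 with an estimated correlation). Il1rl1, the IL-33 receptor of tissue TR, was higher by 5.05 ± 0.41 and 4.80 ± 0.36 (adjusted p = 3.56e-07 and 1.67e-07), and Il1r2, the decoy receptor for IL-1, 287-fold (79.1 to 2370) and 1530-fold (274 to 60500).

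Proliferation genes were higher for 6 of 30 in spleen and 16 in lymph node (7 and 19 adjusted over the list alone), none lower, with the list call lost (adjusted p = 0.398 and 0.0796 with an estimated correlation). Mki67, a marker of cycling cells, was 526-fold (94.1 to 20800) higher in spleen and higher by 4.92 ± 0.51 in lymph node (adjusted p = 4.46e-06). Glycolysis genes gave Tpi1 higher and Eno1 and Ldha lower in spleen, and Tpi1 higher in lymph node (1 and 2, and 0 and 0, adjusted over the list alone), with no list call (adjusted p = 0.52 and 0.949). Without the 3 libraries that stand apart, Tpi1 and Eno1 were not called in spleen (adjusted p = 0.0841 and 0.244). Tpi1 was not called in lymph node without Id3- eTR of mice 84 and 86 (0.0608 and 0.131), without Id3+ cTR of mice 86 and 87 (0.093 and 0.102) or with no filter (0.0559). Sterol and lipid genes gave 0 calls in spleen in edgeR, where limma-voom called Sqle lower (adjusted p = 0.048), and Sqle lower in lymph node (0 and 1 adjusted over the list alone; adjusted p = 0.267 and 0.661 with an estimated correlation). The lymph node call of Sqle ended without Id3- eTR of mouse 84, 86 or 87 (0.0677, 0.0577 and 0.0551), without Id3+ cTR of mouse 84 or 86 (0.0792 and 0.0533) and with limma-voom (0.0716). The interferon list went both ways and was not called (2 higher and 3 lower of 22 in spleen, 1 and 2 in lymph node; 2 and 3, and 1 and 3, adjusted over the list alone; adjusted p = 0.496 and 0.309). Usp18, an interferon-induced protease, was at -1.72 ± 0.34 and -1.76 ± 0.33 (adjusted p = 0.0022 and 0.00166). Dissociation stress genes gave 2 of 19 higher in spleen (Fosb and Dusp1), and 4 higher and 2 (Jun and Ier2) lower in lymph node. The counts were 2 and 0, and 5 and 2, adjusted over the list alone (adjusted p = 0.332 and 0.659 with an estimated correlation). Dusp1, an immediate-early phosphatase, was at 0.47 ± 0.11 and 0.58 ± 0.11 (adjusted p = 0.00895 and 0.00149), and in spleen at adjusted p = 0.0519 without Id3- eTR of mouse 86. The spleen call of Fosb ended without Id3- eTR of mouse 86 or 87 (0.0509 and 0.0732), Id3+ cTR of mouse 84 or 87 (0.0675 and 0.103), or the 3 libraries that stand apart (0.162).

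Markers of other cells moved with this comparison too. Among CD8 T and NK genes, Nkg7 and Ccl5 were higher in spleen, and with Klrk1 in lymph node (4 and 1, and 3 and 0, of 6 adjusted over the list alone; adjusted p = 0.148 and 0.1 with an estimated correlation). Nkg7 was at 1.83 ± 0.34 and 2.68 ± 0.35 (adjusted p = 0.00141 and 4.6e-05). Myeloid genes were higher for 3 of 8 in spleen (Cd68, Fcer1g and Tyrobp) and 4 in lymph node (Fcer1g, Tyrobp, Cst3 and Spi1; 3 and 6 adjusted over the list alone; adjusted p = 0.0562 and 0.0168 with an estimated correlation). In spleen Fcer1g was not called with any 1 of the 6 libraries left out (adjusted p from 0.0783 to 0.164), nor without the 3 libraries that stand apart (0.341), with mouse as a block (0.0655), with no filter (0.0577) or without the densest genes (0.0521). Tyrobp was not called there without Id3- eTR of mouse 87 (0.0516), Id3+ cTR of mouse 84 or 86 (0.068 and 0.0804) or the 3 libraries (0.0582). In lymph node Fcer1g was lost without Id3+ cTR of mouse 87 (0.0562) and in a fit of these groups alone (0.0577), and Tyrobp without Id3- eTR of mouse 87 (0.0582) or Id3+ cTR of mouse 86 (0.0627). B cell genes gave Cd79a lower in spleen and Cd74 and Ighm higher in lymph node of 13 (0 and 1, and 2 and 2, adjusted over the list alone; adjusted p = 0.603 and 0.949). The Cd79a call ended without Id3- eTR of mouse 86 or 87 (adjusted p = 0.0792 and 0.0941), without Id3+ cTR of mouse 86 or 87 (0.109 and 0.057), with limma-voom (0.187), in a fit of these groups alone (0.0615) and with mouse as a block (0.0504). In lymph node a fit of these groups alone called Cd79a too (0.0146). The Cd74 change was 0.93 ± 0.16 in lymph node (adjusted p = 0.000521). Of 8 erythroid and platelet genes only Alas2 was called, lower in spleen (2 and 2, and 0 and 0, adjusted over the list alone). The list had adjusted p = 0.0588 (0.0257 with mouse as a block, not called with an estimated correlation) and 0.949. Alas2 was not called without Id3- eTR of mouse 87 (0.0789) or Id3+ cTR of mouse 86 (0.0624). The conventional CD4 list was not called (5 higher and 2 lower of 10 in spleen, 3 and 2 in lymph node, as many as adjusted over the list alone; adjusted p = 0.133 and 0.402). Pecam1, the 1 tested gene of the endothelial list, was lower at -1.83 ± 0.17 and -1.89 ± 0.17 (adjusted p = 1.55e-06 and 8.83e-07).

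Outside the lists, the largest rises called in both tissues included Arnt2, a bHLH-PAS transcription factor (at least 53.9-fold in spleen and 144-fold in lymph node). Another was Ltb4r1, the leukotriene B4 receptor (at least 67.9-fold, and 338-fold with an interval of 60.2 to 13400). Krt83, a keratin, was at least 47.5-fold and 60.1-fold higher. Ctla2b and Serpina3f, at least 62.6-fold and 165-fold higher in spleen and 100-fold and 35-fold in lymph node, belong to families of near-identical copies whose reads cannot be assigned with certainty. The largest falls included Tdrp, 547-fold (97.6 to 21700) lower in spleen and at least 183-fold in lymph node, and Lad1, an anchoring filament protein, at -6.52 ± 0.77 and -5.69 ± 0.69 (adjusted p = 1.91e-05 and 2.26e-05).

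Id3+ eTR against Id3+ cTR compares the populations that carry the Id3 reporter. Part of the effector program was higher in Id3+ eTR, while Id3 itself was not called (-0.17 ± 0.15 and 0.14 ± 0.15, adjusted p = 0.588 and 0.76). Tigit, an inhibitory receptor, was higher by 4.61 ± 0.34 in spleen and 6.17 ± 0.34 in lymph node (adjusted p = 1.16e-06 and 3.27e-08). Cxcr3, a chemokine receptor of type 1 responses, was higher by 4.97 ± 0.42 and 4.85 ± 0.40 (adjusted p = 2.59e-06 and 1.11e-06). Nrp1, the semaphorin receptor neuropilin-1, was higher by 1.20 ± 0.09 and 1.49 ± 0.09 (adjusted p = 1.16e-06 and 4.06e-08). Satb1, a chromatin organiser of resting T cells, was lower at -1.22 ± 0.12 and -1.95 ± 0.13 (adjusted p = 2.67e-05 and 5.66e-08). Cd44 moved as sorted, at 1.30 ± 0.25 in lymph node and 1.20 ± 0.26 in spleen (adjusted p = 0.00352 and 0.0127). The spleen call of Cd44 ended without Id3+ eTR or Id3+ cTR of mouse 84 (adjusted p = 0.0603 and 0.0585), without the 3 libraries that stand apart (adjusted p = 0.459) and with limma-voom (0.0912).

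Here 538 genes were called in spleen (365 higher and 173 lower in Id3+ eTR) and 705 in lymph node (523 and 182), with 237 higher and 53 lower in both, where independent calls would give 15.3 and 2.53. The spleen count depended on the fit: it was 1023 with DESeq2 and 145 in a fit of these groups alone. It was 69 without the 3 libraries that stand apart (66 higher and 3 lower, 60 of the 69 among the 538), 345 without Id3+ eTR of mouse 84, 301 without Id3+ cTR of mouse 84 and 256 without Id3+ cTR of mouse 87. Higher genes were the larger part in every fit, and least so without Id3+ cTR of mouse 86 (318 and 278). The lymph node count was 458 without Id3+ cTR of mouse 87.

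Effector TR genes were higher for 16 of 24 in each tissue and lower for none (19 and 1, and 18 and 0, adjusted over the list alone; adjusted p = 0.000331 and 8.33e-05 with an estimated correlation). Central and recirculating genes were lower for 10 of 20 in spleen and 13 in lymph node (15, and 16 with 1 higher, adjusted over the list alone; adjusted p = 0.000331 and 0.000136 with an estimated correlation). Tissue TR genes were higher for 11 and 13 of 20 (13 and 16 adjusted over the list alone; adjusted p = 0.00241 and 0.000136 with an estimated correlation). Homing receptors were higher for 8 of 23 in spleen, with Selplg lower, and for 10 in lymph node, with Itga4 lower (9 and 1, and 11 and 5, adjusted over the list alone; adjusted p = 0.00719 and 0.00169 with an estimated correlation). Ccr4, a skin-homing receptor, was 49.9-fold (16.9 to 244) higher in spleen and higher by 3.94 ± 0.54 in lymph node (adjusted p = 0.000214). Suppressive genes were higher for 4 of 15 in spleen (Ebi3, Nt5e, Tigit and Itgb8) and 6 in lymph node (6 and 1, and 7 and 0, adjusted over the list alone; adjusted p = 0.00667 and 0.000412 with an estimated correlation). Ebi3, a subunit of IL-35, was higher by 4.07 ± 0.51 and 3.01 ± 0.43 (adjusted p = 0.000222 and 0.000309). Helper lineage genes were higher for 6 and 5 of 12 (7 and 8 adjusted over the list alone; adjusted p = 0.00719 and 0.000875 with an estimated correlation).

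Follicular TR genes were higher for 5 of 14 in spleen (Pdcd1, Icos, Tox, Tox2 and Angptl2) and 9 in lymph node (7 and 1, and 13 and 0, adjusted over the list alone; adjusted p = 0.0425 and 0.000136 with an estimated correlation). Pdcd1 was higher by 2.64 ± 0.32 and 2.87 ± 0.32 (adjusted p = 0.000172 and 2.55e-05), the first at adjusted p = 0.0683 without the 3 libraries that stand apart. Tox2, a nuclear factor of follicular T cells, was higher by 4.26 ± 0.74 in spleen (adjusted p = 0.00347, and 0.0713 in a fit of these groups alone) and 584-fold (104 to 23100) in lymph node. T cell receptor-induced genes were higher for 6 of 16 in spleen, and 7 with Myc lower in lymph node (7 and 1, and 11 and 1, adjusted over the list alone; adjusted p = 0.0653 and 0.00726 with an estimated correlation). Core TR genes gave 2 of 16 higher in spleen (Nrp1 and Nt5e; 3 and 1 adjusted over the list alone; adjusted p = 0.0704) and 6 in lymph node (8 and 1; adjusted p = 0.00359 with an estimated correlation). In spleen Nt5e was not called in a fit of these groups alone (adjusted p = 0.0781) or without the 3 libraries (0.424), and Angptl2 not in a fit of these groups alone (0.0781). TNF receptor and NF-kB genes gave 4 higher of 17 in each tissue: Tnfrsf1b, Tnfrsf8 and Tnfrsf9 in both, Nfkb2 in spleen and Tnfrsf4 in lymph node. The counts were 6 and 2, and 9 and 1, adjusted over the list alone (adjusted p = 0.191 and 0.00756 with an estimated correlation). The call of Tnfrsf1b ended in lymph node with any 1 of the 6 libraries left out (adjusted p from 0.0505 to 0.117) and with no filter (0.063). It ended in spleen without Id3+ cTR of mouse 84 or 86 (0.0539 and 0.0629), without Id3+ eTR of mouse 84 (0.0691), with limma-voom (0.0855) and in a fit of these groups alone (0.172). Without the 3 libraries Tnfrsf8 and Il1rl1 were not called in spleen (0.189 and 0.115). Cytokine receptor genes gave 4 higher of 24 in spleen (Il10ra, Il12rb1, Il1r2 and Il1rl1) and 6 in lymph node (7 and 1, and 8 and 0, adjusted over the list alone). The list had adjusted p = 0.0545 in spleen (0.0439 with mouse as a block). With an estimated correlation it was not called there or in lymph node (0.0874). Il1r2 was 168-fold (46.2 to 1390) higher in spleen (adjusted p = 0.106 without the 3 libraries and 0.139 with limma-voom) and 2640-fold (473 to 104000) in lymph node.

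Id2 was at 0.92 ± 0.15 in lymph node (adjusted p = 0.000969) and 0.53 ± 0.15 in spleen (adjusted p = 0.0635 in edgeR, 0.0248 without Id3+ eTR of mouse 84, and 0.0227 in DESeq2), with no call for a difference between the tissues (interaction adjusted p = 0.58). It was the only member of its list called (0 and 1 of 6, and 2 and 1 adjusted over the list alone; adjusted p = 0.281 and 0.121). Proliferation genes gave Mki67 higher in both tissues and Mcm6 in lymph node (1 and 5 of 30 adjusted over the list alone; adjusted p = 0.829 and 0.325 with an estimated correlation). Mki67 was at 3.03 ± 0.50 in lymph node (adjusted p = 0.00117), and in spleen was not called with limma-voom (0.203) or without the 3 libraries (0.194). Mcm6 was not called without Id3+ cTR of mouse 86 or 87 (0.201 and 0.108) or Id3+ eTR of mouse 84 or 87 (0.135 and 0.149). Glycolysis, sterol, interferon and stress genes gave at most 1 call each in edgeR: Ldha lower and Igtp lower in spleen, and Tpi1 higher, Gbp2 lower and Dusp1 higher in lymph node. DESeq2 also called Tpi1 in spleen (adjusted p = 0.0222, and in edgeR 0.0394 and 0.0488 without Id3+ eTR of mouse 84 or 86) and Igtp in lymph node (0.0435, and 0.033 in limma-voom). Ldha was not called without Id3+ cTR of mouse 84 or 87 (0.143 and 0.177), Id3+ eTR of mouse 84, 86 or 87 (0.0604, 0.0671 and 0.0974), or the 3 libraries (0.832), nor in a fit of these groups alone (0.204). Igtp was not called in spleen without Id3+ cTR of mouse 84 or 87 (0.0624 and 0.162), Id3+ eTR of mouse 84 or 87 (0.131 and 0.0593), or the 3 libraries (0.635). Nor was it with mouse as a block (0.0526), with no filter (0.0588), with limma-voom (0.0511) or in a fit of these groups alone (0.212). Gbp2 was not called without Id3+ cTR of mouse 84, 86 or 87 (0.095, 0.061 and 0.141) or Id3+ eTR of mouse 86 or 87 (0.117 and 0.149). Their lists were not called in spleen (adjusted p = 0.271, 0.509, 0.125 and 0.773) or lymph node (0.316, 0.13, 0.16 and 0.309). In spleen, adjusted over the list alone, they gave 1 higher and 1 lower, 0 and 0, 2 and 3, and 0 and 0, and in lymph node 1 and 0, 0 and 0, 0 and 3, and 1 and 0.

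Among markers of other cells, Nkg7 and Ccl5 were called in lymph node, at 2.55 ± 0.35 and 4.36 ± 0.64 (adjusted p = 0.000206 and 0.000399), and stood at 0.16 ± 0.34 and 1.51 ± 0.66 in spleen (adjusted p = 0.841 and 0.213). The difference between the tissues was not past the threshold for Nkg7 or Ccl5 (interaction adjusted p = 0.225 and 0.39). Of the 6 genes of that list, 0 in spleen and 3 in lymph node were higher adjusted over the list alone (adjusted p = 0.556 and 0.0759 with an estimated correlation). Of 13 B cell genes only Cd74 was called, at 0.81 ± 0.16 in lymph node (adjusted p = 0.00379; 0 and 2 adjusted over the list alone). The list had adjusted p = 0.0757 (0.0439 with mouse as a block, not called with an estimated correlation) and 0.634. Myeloid genes gave 0 calls in either tissue (0 and 4 of 8 adjusted over the list alone; adjusted p = 0.493 and 0.0448 with an estimated correlation). Erythroid genes gave 0 calls as well (0 and 0 of 8 adjusted over the list alone), with the list lower in spleen at a preset correlation and the call lost (adjusted p = 0.244 with an estimated correlation; 0.677 in lymph node). Conventional CD4 genes gave 3 higher and 1 lower of 10 in spleen (Tnfsf14, Ifng, Il4; Themis), and 4 higher (with Cd40lg) and 1 lower in lymph node (5 and 2 in each adjusted over the list alone; adjusted p = 0.398 and 0.131). In spleen Tnfsf14 and Il4 were not called without the 3 libraries (0.25 and 0.196), and Tnfsf14 not with limma-voom (0.0875). Pecam1 was at -0.92 ± 0.16 in lymph node (adjusted p = 0.00199), and in spleen at -0.80 ± 0.16 (adjusted p = 0.00899, and 0.147 without the 3 libraries that stand apart). Outside the lists, Krt83 was at least 21.7-fold higher in spleen and 67.2-fold in lymph node. Rasgrp2, an activator of Rap1, was at -1.39 ± 0.18 in lymph node (adjusted p = 0.000155) and -0.87 ± 0.18 in spleen (adjusted p = 0.0104, and 0.324 without the 3 libraries).

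Id3- eTR against Id3+ eTR is the step at which Id3 is lost. Id3 was at -2.09 ± 0.16 in spleen and -2.05 ± 0.16 in lymph node (adjusted p = 1.14e-06 and 9.23e-07), and Id2 rose from 126 ± 27.4 to 357 ± 39.6 CPM (SD) and from 199 ± 23.1 to 361 ± 10.9 (adjusted p = 1.5e-05 and 0.00241). Ccr2 was 820-fold (280 to 3980) higher in spleen and higher by 7.20 ± 0.32 in lymph node (adjusted p = 1.13e-09), and Il10 was higher by 4.36 ± 0.62 and 6.54 ± 0.72 (adjusted p = 0.00049 and 4.08e-05). Gzmb, the cytotoxic protease granzyme B, was higher by 5.23 ± 0.84 in spleen (adjusted p = 0.00155) and 733-fold (251 to 3560) in lymph node. Igfbp4 was at -5.32 ± 0.51 and -5.03 ± 0.51 (adjusted p = 1.09e-05 and 1.84e-05). Cd44 was not called in edgeR (0.63 ± 0.24 and 0.62 ± 0.24, adjusted p = 0.179 and 0.232), while limma-voom called it higher in lymph node (adjusted p = 0.0398).

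The counts were 408 genes in spleen (190 higher and 218 lower in Id3- eTR) and 326 in lymph node (181 and 145), with 95 higher and 78 lower in both, where independent calls would give 2.76 and 2.54. In spleen 354 genes were called without the 3 libraries that stand apart (260 of them among the 408), and 267 without Id3- eTR of mouse 87. In lymph node 200 were called without Id3- eTR of mouse 84 and 192 without Id3+ eTR of mouse 87. DESeq2 called 735 and 554 in spleen and lymph node, limma-voom called 636 in lymph node, and a fit of these groups alone called 171 in spleen. The balance of higher and lower was not stable. In spleen it was 249 and 183 with limma-voom, 101 and 70 in a fit of these groups alone, 195 and 159 without the 3 libraries, and 196 and 172 without Id3+ eTR of mouse 84. In lymph node it was 95 and 105, 107 and 114, and 109 and 111 without Id3- eTR of mouse 84, 86 or 87, and 108 and 117 without Id3+ eTR of mouse 86.

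Effector TR genes were higher for 15 and 16 of 24, none lower (19 and 17 adjusted over the list alone; adjusted p = 1.73e-05 and 2.12e-05 with an estimated correlation). Icos, a costimulatory receptor, was higher by 1.35 ± 0.11 and 1.03 ± 0.10 (adjusted p = 1.14e-06 and 1.84e-05). Homing receptors were higher for 9 of 23 in spleen and 8 in lymph node, with Itga4 lower there (15 and 1, and 12 and 2, adjusted over the list alone; adjusted p = 1.73e-05 and 5.38e-05 with an estimated correlation). Suppressive genes were higher for 6 of 15 in each tissue (10 and 9 adjusted over the list alone; adjusted p = 6.19e-05 and 5.38e-05 with an estimated correlation). Tissue TR genes were higher for 7 and 6 of 20 (12 and 7 adjusted over the list alone; adjusted p = 0.00037 and 0.000675 with an estimated correlation). Helper lineage genes were higher for 5 of 12 in spleen and 3 in lymph node, Cxcr3 among them in both (11 and 6 adjusted over the list alone; adjusted p = 6.19e-05 and 0.00123 with an estimated correlation). In lymph node the call of Cxcr3 ended with any 1 of the 6 libraries left out (adjusted p from 0.0568 to 0.149). Central and recirculating genes were lower for 14 and 10 of 20 (18 and 12 lower and 1 and 1 higher adjusted over the list alone; adjusted p = 6.21e-05 and 0.000922 with an estimated correlation). Cytokine receptor genes gave 4 higher (Il18r1, Il1rl1, Ifngr1 and Socs2) and Il6ra lower of 24 in spleen, and 5 higher (Il10ra, Il18r1, Il1rl1, Socs2 and Cish) in lymph node. The counts were 8 and 6, and 8 and 3, adjusted over the list alone (adjusted p = 0.0631 and, in lymph node, 0.0683 with an estimated correlation). In lymph node Il18r1 was not called without Id3- eTR of mouse 84 or 87 (0.0833 and 0.0605) or Id3+ eTR of mouse 86 or 87 (0.083 and 0.086). Socs2 was not called there without Id3- eTR of mouse 87 (0.0708) or Id3+ eTR of mouse 86 or 87 (0.0555 and 0.0903), nor in spleen in a fit of these groups alone (0.164). Il1rl1 rose by 2.13 ± 0.32 and 3.25 ± 0.33 (adjusted p = 0.000749 and 1.84e-05).

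Follicular TR genes gave Icos higher in both tissues and Tnfsf8 lower in lymph node of 14 (2 and 1, and 1 and 5, adjusted over the list alone). The list was not called in spleen (adjusted p = 0.385), and its lower place in lymph node was lost (adjusted p = 0.221 with an estimated correlation). Tnfsf8, which encodes CD30 ligand, was at -1.06 ± 0.15 in lymph node (adjusted p = 0.00057) and -0.56 ± 0.15 in spleen (adjusted p = 0.0558 in edgeR, 0.0476 without Id3+ eTR of mouse 86, 0.046 with no filter, and 0.0168 in DESeq2). T cell receptor-induced genes gave Ctla4 higher and Myc lower, with Nr4a2 lower in lymph node, of 16 (1 and 1, and 1 and 3, adjusted over the list alone; adjusted p = 0.643 and 0.27). Myc fell from 187 ± 15.8 to 93.2 ± 15.8 CPM in spleen and from 164 ± 22.1 to 66.9 ± 7.55 in lymph node (adjusted p = 0.000963 and 0.000119). TNF receptor and NF-kB genes gave 0 calls in edgeR (4 and 1, and 0 and 0, of 17 adjusted over the list alone; adjusted p = 0.301 and 0.592). The spleen call of Ctla4 ended without Id3- eTR of mouse 86 (0.0909), Id3+ eTR of mouse 84 (0.0564) or the 3 libraries that stand apart (0.0589), and in a fit of these groups alone (0.112). In lymph node it ended without Id3- eTR of mouse 84, 86 or 87 (0.129, 0.105 and 0.0783) or Id3+ eTR of mouse 86 or 87 (0.162 and 0.198), and in a fit of these groups alone (0.0983). Core TR genes gave Ctla4, Capg and Socs2 higher and Lrrc32 and Gpr83 lower of 16 in spleen, and Ctla4 and Socs2 higher and Nrp1 and Gpr83 lower in lymph node (6 and 4, and 5 and 4, adjusted over the list alone; adjusted p = 0.377 and 0.592). Gpr83 was at -1.59 ± 0.18 and -1.30 ± 0.18 (adjusted p = 5.25e-05 and 0.000328). Of the E and Id genes only Id2 and Id3 were called (1 and 2, and 1 and 1, of 6 adjusted over the list alone; adjusted p = 0.142 and 0.592).

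Proliferation genes gave Mki67 and Hmgb2 higher in spleen and Mki67 in lymph node of 30 (4 and 1 adjusted over the list alone; adjusted p = 0.418 and 0.0922 with an estimated correlation). Mki67 rose by 3.03 ± 0.47 in spleen (adjusted p = 0.000983) and 1.89 ± 0.43 in lymph node (adjusted p = 0.0224). The latter was at adjusted p = 0.109, 0.0619, 0.112 and 0.13 without Id3- eTR of mice 84 and 87 and Id3+ eTR of mice 86 and 87, and 0.0605 in a fit of these groups alone. Hmgb2 was not called with any 1 of the 6 libraries left out (adjusted p from 0.0533 to 0.179), nor in a fit of these groups alone (0.321), with no filter (0.214), with mouse as a block (0.0601) or without the 3 libraries (0.0853). Interferon genes gave Usp18 lower in both tissues and Gbp7 higher in lymph node of 22 (0 and 2, and 1 and 2, adjusted over the list alone; adjusted p = 0.575 and 0.944). In spleen Usp18 was not called without Id3- eTR of mouse 84, 86 or 87 (0.0617, 0.0671 and 0.11), Id3+ eTR of mouse 86 (0.0829) or the 3 libraries (0.0502). In lymph node it was not called without Id3- eTR of mouse 84 or 86 (0.16 and 0.131), without Id3+ eTR of mouse 84 or 87 (0.0789 and 0.223), with no filter (0.0558) or in a fit of these groups alone (0.179). Glycolysis, sterol and stress genes gave 0 calls in edgeR, also adjusted over the list alone (adjusted p = 0.585 and 0.27, 0.324 in spleen with an estimated correlation and 0.971, and 0.324 in spleen with an estimated correlation and 0.592). Among markers of other cells, Nkg7 and Ccl5 were higher in spleen at 1.66 ± 0.33 and 3.22 ± 0.56 (adjusted p = 0.00767 and 0.00276). They stood at 0.13 ± 0.31 and -0.12 ± 0.50 in lymph node (adjusted p = 0.934 and 0.968; interaction 0.51 for Nkg7 and 0.202 for Ccl5). Their list gave 3 and 0 of 6 higher adjusted over the list alone and was not called (adjusted p = 0.0746 and 0.783). B cell, myeloid, erythroid and conventional CD4 genes gave 0 calls in either tissue; adjusted over the list alone the B cell list gave 1 higher in spleen and the conventional list 1 higher and 2 lower in lymph node. Those lists had adjusted p = 0.301, 0.0679 (with an estimated correlation), 0.987 and 0.214 in spleen, and 0.783, 0.101, 0.853 and 0.783 in lymph node. Pecam1 was at -1.03 ± 0.17 and -0.96 ± 0.17 (adjusted p = 0.00159 and 0.00344). Outside the lists, Ltb4r1 was 288-fold (51.3 to 11400) and 151-fold (41.4 to 1250) higher in spleen and lymph node. Lad1 was at -5.63 ± 0.77 and -4.74 ± 0.69 (adjusted p = 0.00038 and 0.00057), and Arhgap20 at -4.18 ± 0.65 and -3.67 ± 0.58 (adjusted p = 0.00103 and 0.00152).

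**Figure D3:**
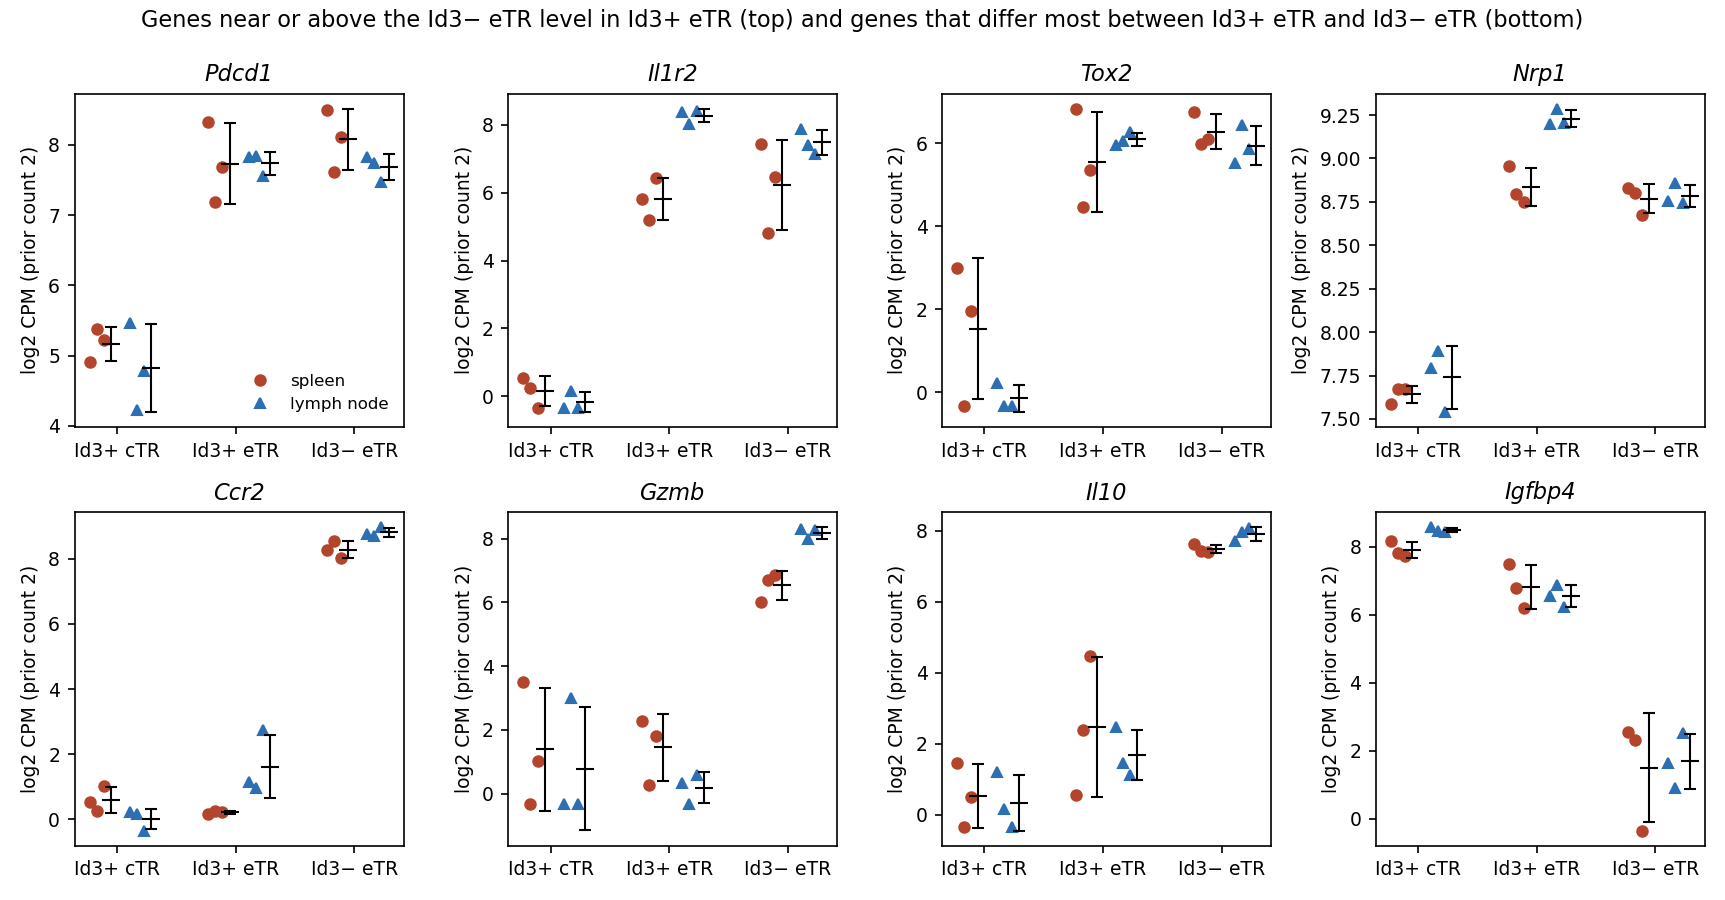
Expression (vertical axes, log2 CPM with a prior count of 2) of 8 genes in each population and tissue; points are libraries and the dash with bar is the mean ± SD of 3 mice. Pdcd1, Il1r2, Tox2 and Nrp1 in the top panels are near or above the Id3- eTR level in Id3+ eTR. In the bottom panels Ccr2, Gzmb, Il10 and Igfbp4 differ most between Id3+ eTR and Id3- eTR. Ccr2 is at 0.377 and 313 CPM on average in spleen before the log.

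Between the ends of the path, Id3+ eTR stood about midway. For genes that separate Id3- eTR from Id3+ cTR in the other tissue, Id3+ eTR had covered a share of 0.446 ± 0.020 (SD, n = 3 mice, 1030 genes) of the log2 distance in spleen and 0.597 ± 0.011 (n = 3, 934 genes) in lymph node. On the log2 scale that share was larger for genes that rose (0.522 in spleen, 0.663 in lymph node) than for genes that fell (0.289 and 0.469). On the CPM scale, over a narrower set of such genes with at least 20 CPM, the order was the reverse, with medians of 0.375 and 0.491 in spleen (508 genes) and 0.463 and 0.648 in lymph node (519 genes). Which direction lay nearer to Id3- eTR thus depends on the scale and the genes taken. Genes that rose at both steps numbered 57 in spleen and 51 in lymph node, with 28 in common, and genes that fell at both steps 26 and 25, with 10 in common. Independent calls would give 5.57, 7.61, 3.03 and 2.12. Chosen after their values were seen, Icos, Tigit and Satb1 were examples: Icos rose from 193 through 318 to 812 CPM in spleen, Tigit from 3.45 through 86.9 to 268, and Satb1 fell from 762 through 328 to 113.

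Some genes peaked or dipped in Id3+ eTR. In lymph node 20 genes were called above both other populations and 14 below both, where independent calls would give 6.09 and 2.65. In spleen there were 3 above (Atp11a, Tbc1d4 and Slc27a4) and 2 below (Cmtm7 and Ly6a), against 6.39 and 2.64. Tbc1d4, a regulator of glucose transport, was the 1 gene above both others in both tissues, at 307 ± 14.8 CPM in spleen against 144 ± 20.4 in Id3+ cTR and 199 ± 42.5 in Id3- eTR. In lymph node it was at 420 ± 20.5 against 153 ± 26.7 and 168 ± 19.4. Ly6a, a member of a family of close copies, was the 1 below both, at 189 ± 26.3 CPM in spleen against 298 ± 48.6 and 339 ± 43.6. In lymph node the genes above both included Nrp1, at 600 ± 20.6 CPM against 214 ± 26.2 and 440 ± 20.1, and Cd200, which encodes an inhibitory ligand, at 328 ± 42.7 against 181 ± 24.6 and 190 ± 19.3. Cxcr5, the follicle-homing receptor, had means of 171 ± 67.6 in spleen Id3+ eTR against 54.0 ± 17.8 and 76.2 ± 12.2, but it was called in lymph node against Id3+ cTR alone (1.77 ± 0.48, adjusted p = 0.0378). These genes were also chosen after their values were seen. Both steps share the Id3+ eTR libraries, so part of such a count can come from their error. The log2 changes of the steps correlated at -0.50 and -0.53 across genes in simulated data in which nothing changed, with 0 genes called.

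Between the tissues, few genes were called within a population in edgeR. Tissue cannot be told from preparation or library order, as spleen libraries are numbered first. Itga4, the alpha-4 integrin that binds vessel walls of gut and inflamed tissue, was lower in lymph node than spleen by -2.06 ± 0.12 in Id3- eTR (adjusted p = 8.35e-08) and -1.05 ± 0.12 in Id3+ eTR (adjusted p = 0.00039, and 0.0902 in a fit of these groups alone). In Id3+ cTR Itga4 was at -0.30 ± 0.12 (adjusted p = 0.537). Icos was higher in lymph node by 0.64 ± 0.10 in Id3- eTR (adjusted p = 0.0113, and 0.0575 without lymph node Id3- eTR of mouse 84) and 0.96 ± 0.11 in Id3+ eTR (adjusted p = 0.00039, and 0.0902 in a fit of these groups alone). Gcnt1, an enzyme of O-glycan branching, was higher by 3.26 ± 0.50 in lymph node Id3- eTR (adjusted p = 0.00907), and Gimap7, a GTPase of lymphocytes, lower at -0.97 ± 0.14 (adjusted p = 0.00538). Apol9a, 1 of a pair of near-identical genes, was higher by 1.97 ± 0.28 in Id3- eTR, 2.18 ± 0.28 in Id3+ eTR and 2.08 ± 0.29 in Id3+ cTR (adjusted p = 0.00538, 0.00169 and 0.0206). In a fit of the groups compared alone the first and second of these were at 0.0936 and 0.0902. In Id3+ cTR Apol9a was the only gene called, and its call was lost without spleen Id3+ cTR of mouse 84 (0.147) or 87 (0.109) or lymph node Id3+ cTR of mouse 84 (0.0862) or 87 (0.119), and without the 3 libraries (0.276).

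Lymph node against spleen gave 38 genes in Id3- eTR (18 higher and 20 lower), 36 in Id3+ eTR (14 and 22) and 1 in Id3+ cTR. At an unadjusted p under 0.05 there were 984, 1477 and 967 genes. DESeq2 called 145, 195 and 71, and limma-voom 99, 31 and 2. In edgeR fits of the groups compared alone the counts were 23, 0 and 6, so no call in Id3+ eTR held there. With no filter Id3+ eTR gave 62, and without the densest genes 14. In the simulated data the contrast in Id3+ cTR called 32% of the genes changed by 2-fold, so a low count leaves room for differences not called. The balance of higher and lower changed with the tool: DESeq2 gave 76 and 69 in Id3- eTR and 22 and 49 in Id3+ cTR, and limma-voom 54 and 45 in Id3- eTR and 18 and 13 in Id3+ eTR. Without the 3 libraries that stand apart, Id3+ eTR gave 9 (7 of them among the 36) and Id3+ cTR 1 (0 in common). The Id3- eTR count was 22 without spleen mouse 86, and 15 and 18 without lymph node mice 84 and 87. The Id3+ eTR count was 10 and 12 without spleen mice 84 and 86, and 5, 16 and 13 without lymph node mice 84, 86 and 87. For Id3+ cTR it was 0 without spleen mouse 84, spleen mouse 87 or lymph node mouse 87, 24 without spleen mouse 86 and 3 without lymph node mouse 86; with mouse as a block it was 2.

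In Id3- eTR, suppressive, effector TR, tissue TR and core TR genes stood higher in lymph node as lists (adjusted p = 0.00161, 0.01, 0.0271 and 0.0255 with an estimated correlation). Few members were called: Icos and Itgae for the effector list and Itgae for the tissue list (1, 2, 1 and 4 higher adjusted over the list alone). Dissociation stress genes stood lower in lymph node (0 of 19 called, 8 lower adjusted over the list alone; adjusted p = 0.0271 with an estimated correlation). Calls of proliferation (3 higher adjusted over the list alone), cytokine receptor (4 and 1) and erythroid genes (6 lower) were lost, with adjusted p = 0.0615, 0.141 and 0.124 with an estimated correlation. In Id3+ eTR, central and recirculating genes stood lower in lymph node, with S1pr1, Klf2, Klf3 and Satb1 called (8 lower adjusted over the list alone; adjusted p = 0.0296 with an estimated correlation). Satb1 was at -0.97 ± 0.12 (adjusted p = 0.00169). Follicular genes stood higher, with Icos and Tox called (5 adjusted over the list alone; adjusted p = 0.0341 with an estimated correlation). So did core and tissue TR genes, each at adjusted p = 0.049 with an estimated correlation. Capg of the core list was called, and 0 tissue TR genes in edgeR (5, and 6 and 1, adjusted over the list alone). Calls of effector, suppressive, proliferation, sterol, stress and erythroid genes were lost in Id3+ eTR (adjusted p = 0.0584, 0.0584, 0.252, 0.108, 0.175 and 0.175 with an estimated correlation). Adjusted over the list alone they gave 6 higher and 1 lower, 2 and 0, 3 and 0, 2 and 8, 0 and 3, and 0 and 4. For the effector and suppressive lists the mean change was -0.12 and -0.54 while the median was 0.23 and 0.13 and the test pointed up. With mouse as a block the TNF receptor and the CD8 and NK lists (adjusted p = 0.0633 and 0.11) were at 0.0299. Neither was called with an estimated correlation. In Id3+ cTR the central, sterol, stress and erythroid lists stood lower in lymph node at a preset correlation, with 2, 3, 7 and 6 genes lower adjusted over the list alone. None of these held (adjusted p = 0.101, 0.298, 0.101 and 0.101 with an estimated correlation). The other 14 lists in Id3- eTR, 12 in Id3+ eTR and 18 in Id3+ cTR were not called at the preset correlation.

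**Figure D4:**
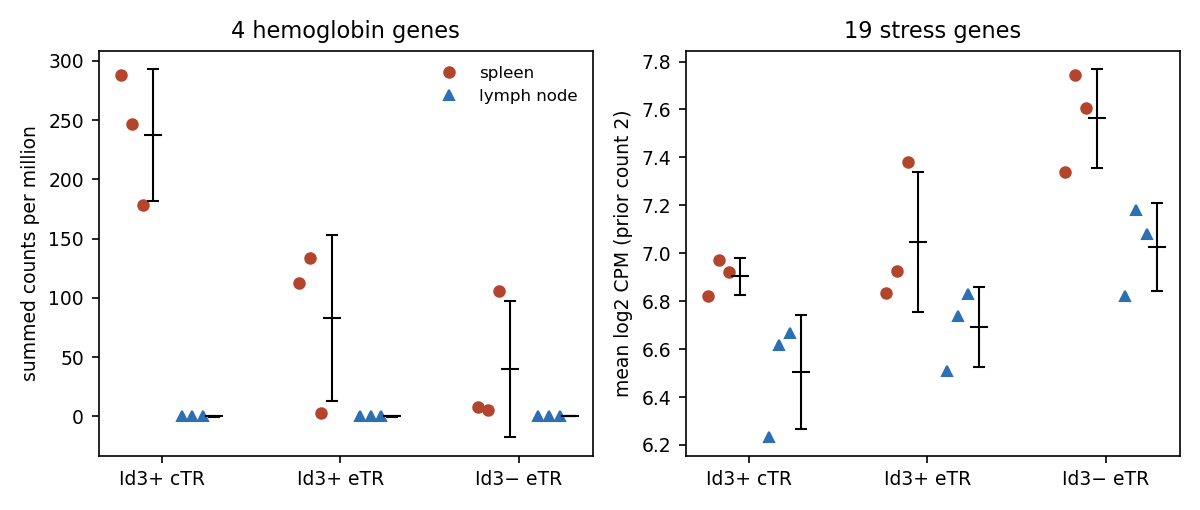
Summed CPM of 4 hemoglobin genes (left) and mean log2 CPM of 19 dissociation stress genes (right) in each group; points are libraries and the dash with bar is the mean ± SD of 3 mice. Hemoglobin reaches 238 CPM on average in spleen Id3+ cTR and is near 0 in every lymph node group, and stress genes are higher in spleen in 9 of 9 pairs of libraries from the same mouse and population.

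Hemoglobin transcripts, which mature T cells do not make in quantity, stood at 238 ± 55.4 CPM (SD, n = 3) in spleen Id3+ cTR, 83.2 ± 70.2 in spleen Id3+ eTR and 39.8 ± 57.3 in spleen Id3- eTR, against 2 counts in all 9 lymph node libraries. Hspa1a, an inducible heat shock gene of the stress list, had means of 128 ± 56.5, 74.7 ± 18.6 and 42.2 ± 22.8 CPM in spleen Id3- eTR, Id3+ eTR and Id3+ cTR, and 17.2 ± 14.5, 15.0 ± 13.8 and 15.2 ± 13.4 in lymph node.

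The interaction tests ask whether a population difference itself differs between the tissues. From Id3+ cTR to Id3- eTR, Itga4 rose in spleen, from 493 ± 39.7 to 763 ± 57.3 CPM (0.63 ± 0.12, adjusted p = 0.00134). It fell in lymph node, from 402 ± 8.93 to 183 ± 28.9 (-1.13 ± 0.12, adjusted p = 4.85e-06), an interaction of -1.76 ± 0.17 (adjusted p = 0.000109). P2rx7, the ATP-gated receptor that makes T cells sensitive to extracellular ATP, was at 0.62 ± 0.20 in spleen (adjusted p = 0.0534) and -1.21 ± 0.21 in lymph node (adjusted p = 0.000661), an interaction of -1.83 ± 0.29 (adjusted p = 0.038). Cdca7l, a Myc-interacting nuclear protein, was at 1.14 ± 0.20 in spleen (adjusted p = 0.00083) and -0.59 ± 0.19 in lymph node (adjusted p = 0.0504), an interaction of -1.73 ± 0.28 (adjusted p = 0.038). These 3 genes, all with a more negative difference in lymph node, were the only ones called by edgeR in the 3 interactions. The counts were 3 for Id3- eTR against Id3+ cTR, 0 for Id3+ eTR against Id3+ cTR (1180 at an unadjusted p under 0.05) and 0 for Id3- eTR against Id3+ eTR (750). DESeq2 called 49 (40 with a more positive difference in lymph node), 66 and 37, and limma-voom called 2, 0 and 3. With no filter the third count was 4. The count of 3 was 1 in a fit of the groups compared alone, 2 without the 3 libraries that stand apart, and 5 without spleen Id3- eTR of mouse 86. It was 2 without lymph node Id3- eTR of mouse 86 or 87 or lymph node Id3+ cTR of mouse 86. The second count was 1 without lymph node Id3+ cTR of mouse 84 or 86. The third was 1 without the 3 libraries, without spleen Id3+ eTR of mouse 84 or without lymph node Id3- eTR of mouse 86, 2 without spleen Id3+ eTR of mouse 86, and 5 without lymph node Id3- eTR of mouse 87. The first count was 1 without spleen Id3- eTR of mouse 84 or 87, spleen Id3+ cTR of mouse 84, 86 or 87, lymph node Id3- eTR of mouse 84, or lymph node Id3+ cTR of mouse 84 or 87. P2rx7 lost its call without each of the 12 libraries (adjusted p from 0.0702 to 0.158) except Id3- eTR of mouse 86 from spleen or lymph node. Cdca7l lost its call without each of them (0.0539 to 0.183) except spleen Id3- eTR and lymph node Id3+ cTR of mouse 86. Without the 3 libraries that stand apart they were at 0.266 and 0.171, and in a fit of these groups alone at 0.12 and 0.121. Itga4 held without the 3 libraries and in every fit that left out 1 library.

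Counts of the most densely covered genes hardly followed the library totals. In genes with 0.03 to 0.1 counts per exon base the median slope of log2 count on log2 total was 1.10 within groups over 18 libraries (3681 genes). It was 0.603 at 0.3 to 0.5 counts per base (219 genes) and 0.456 at 0.5 to 0.75 (78 genes). Actb, a cytoskeletal gene, had 1627 to 2027 counts in every library, and B2m of MHC class I 1250 to 1472. For the 337 genes over 0.3 counts per base, the spleen changes against Id3+ cTR, which holds the 2 libraries with the lowest totals, had medians of -0.24 (Id3- eTR) and -0.35 (Id3+ eTR), against 0.00 and 0.03 in lymph node. Small changes of such genes in spleen are therefore uncertain.

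**Figure D5:**
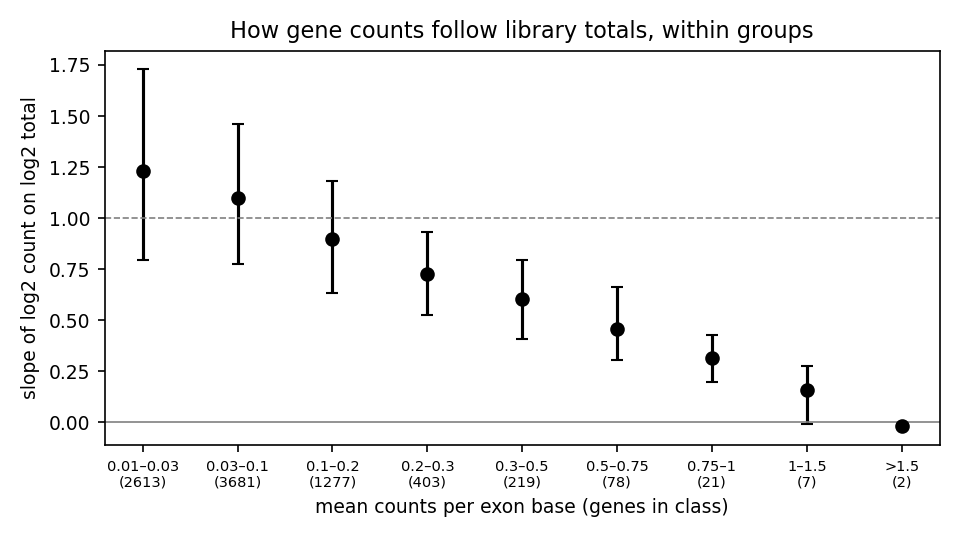
Median slope of log2 count on log2 library total (vertical axis) by counts per exon base (horizontal axis, in classes); points are medians over the genes of each bin and bars the quartiles. The median falls from 1.23 at 0.01 to 0.03 counts per base to 0.456 at 0.5 to 0.75; the 3 densest bins hold 21, 7 and 2 genes.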

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

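Of the tests in this part, the regroupings of the libraries and the fit without the 3 libraries that stand apart were chosen after the result was seen. Itga4, P2rx7 and Cdca7l are singled out because the change from Id3+ cTR to Id3- eTR differed between the tissues in a test of that difference. Itga4 had an interaction of -1.76 ± 0.17 on the log2 scale (adjusted p = 0.000109), opposite in direction in spleen and lymph node in 3 of 3 mice, and kept its call in every alternative, with adjusted p from 4.46e-22 (DESeq2) to 0.00144 (without the 3 libraries that stand apart). P2rx7 had -1.83 ± 0.29 (adjusted p = 0.038 in edgeR, negative in 3 of 3 mice), with a range over its alternatives from 7.66e-06 (DESeq2) to 0.266 (without the 3 libraries). Cdca7l had -1.73 ± 0.28 (adjusted p = 0.038 in edgeR, negative in 3 of 3 mice), with a range from 5.75e-05 (DESeq2) to 0.183 (without spleen Id3+ cTR of mouse 86).

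P2rx7 lost its call without spleen Id3- eTR of mouse 84 (0.12) or 87 (0.0876), spleen Id3+ cTR of mouse 84 (0.158), 86 (0.0702) or 87 (0.0911), lymph node Id3- eTR of mouse 84 (0.133) or 87 (0.134), or lymph node Id3+ cTR of mouse 84 (0.137), 86 (0.0954) or 87 (0.086). Cdca7l lost its call without spleen Id3- eTR of mouse 84 (0.12) or 87 (0.17), spleen Id3+ cTR of mouse 84 (0.0967), 86 (0.183) or 87 (0.0911), lymph node Id3- eTR of mouse 84 (0.0539), 86 (0.112) or 87 (0.134), or lymph node Id3+ cTR of mouse 84 (0.137) or 87 (0.154). A fit of the 4 groups alone left P2rx7 at 0.12 and Cdca7l at 0.121.

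Chance cannot be excluded for the count of these genes: with the tissues redrawn within each population in 100 of 200 possible ways, 7 gave 3 genes or more. Apart from the real split and an exchange of the tissues these are 5 splits, with 4 or 5 genes. The redraw took no account of which libraries came from the same mouse. The highest of the other splits gave 46, several times the real count of 3. That split exchanges spleen and lymph node in 1 of the populations, which adds up the tissue differences in place of subtracting them and so points to a structure of the samples; without it the highest was 5. For Id3+ eTR against Id3+ cTR and for Id3- eTR against Id3+ eTR the real count in edgeR was 0 (1180 and 750 genes at an unadjusted p under 0.05; 66 and 37 with DESeq2, 0 and 3 with limma-voom), so all 100 splits gave as many, with highest counts of 40 and 136 at the same exchange and 12 and 10 otherwise.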

How the results depend on the processing

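Chosen after seeing the data were the fits without the densest genes and without the 3 libraries that stand apart; the others were planned. Of 321 results for named genes, 266 were past the threshold, 177 of these kept their call in every alternative, 56 lost it without some library, and 0 reversed. Calls lost numbered 1 with RLE size factors, 6 with no filter, 9 with mouse as a block, 0 with DESeq2, 23 with limma-voom, 36 of 311 in fits of the groups compared alone, 5 of 299 without the densest genes and 47 of 167 without the 3 libraries. Calls gained numbered 1 with no filter, 6 with DESeq2, 3 with limma-voom and 1 in fits of the groups alone.

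DESeq2 called more genes: 1023 for Id3+ eTR against Id3+ cTR and 735 for Id3- eTR against Id3+ eTR in spleen, 554 for the latter in lymph node, and between the tissues 145 in Id3- eTR, 195 in Id3+ eTR and 71 in Id3+ cTR. Its interactions gave 49, 66 and 37. Limma-voom called 636 for Id3- eTR against Id3+ eTR in lymph node, 99 between the tissues in Id3- eTR, 2 in Id3+ cTR, and 3 in the interaction of Id3- eTR against Id3+ eTR. Fits of the groups alone have fewer libraries to estimate the spread. In spleen they called 145 for Id3+ eTR against Id3+ cTR and 171 for Id3- eTR against Id3+ eTR. In lymph node they called 696 and 374, where the fit of all 18 libraries called 705 and 326. Fewer libraries alone thus do not explain the spleen counts. Between the tissues such fits called 23 in Id3- eTR, 0 in Id3+ eTR in edgeR and 6 in Id3+ cTR, and 1 in the interaction of Id3- eTR against Id3+ cTR. Between the tissues, Id3+ eTR gave 62 with no filter and 14 without the densest genes, and Id3+ cTR 2 with mouse as a block.

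Without the 3 libraries, which leaves spleen Id3+ cTR with 1 library assumed to vary like the others, the spleen counts were 730 for Id3- eTR and 69 for Id3+ eTR against Id3+ cTR. Between the tissues 9 genes were called in Id3+ eTR, and 1 in the interaction of Id3- eTR against Id3+ eTR. Apart from the smaller number of libraries, the cause of these changes was not tested.

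Leaving out 1 library at a time gave 1072 to 1337 genes for Id3- eTR against Id3+ cTR, 256 to 645 for Id3+ eTR against Id3+ cTR and 267 to 440 for Id3- eTR against Id3+ eTR in spleen. In lymph node it gave 1118 to 1266, 458 to 542 and 192 to 235. Between the tissues it gave 15 to 32 in Id3- eTR, 5 to 46 in Id3+ eTR and 0 to 24 in Id3+ cTR, and in the interactions 1 to 5, 0 to 1 and 0 to 5. The counts of 0 are those of edgeR. The step share ranged from 0.435 to 0.453 in spleen and 0.592 to 0.603 in lymph node.

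With the correlation within lists estimated, the lists called fell from 16 to 6 for Id3- eTR against Id3+ cTR and from 10 to 6 for Id3- eTR against Id3+ eTR in spleen, and between the tissues from 8 to 5 in Id3- eTR, 10 to 4 in Id3+ eTR and 4 to 0 in Id3+ cTR. With fry the last was also 0. The step share was 0.411 in spleen and 0.564 in lymph node with no fold minimum, 0.522 and 0.663 over genes that rose, and 0.289 and 0.469 over genes that fell. Depth limits genes of few counts, whose folds are bounds or wide intervals.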

Other observations

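The tests in this part were chosen after the result was seen, except the comparison of shares across the tissues and the ratio of hemoglobin genes.

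Counts of the densest genes, such as Actb and B2m, hardly followed the library totals. A few genes taking most of the counts is argued against, since the 100 highest genes held at most 9.50% of the counts of any library. A limited number of distinct read positions per gene, as removal of duplicate reads would leave, is a candidate explanation: among 2473 genes with 300 to 1000 counts, the longest genes had a median slope 0.16 above the shortest (3 equal classes of length) (bootstrap interval 0.115 to 0.215). Whether duplicates were removed is not stated in the sources used here. No biological explanation was tested.

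Id3+ eTR lie between the other populations, which a mixture of Id3+ cTR and Id3- eTR cells in the sort gate would also produce. Such a mixture alone is argued against in both tissues. Genes' shares of the distance had interquartile ranges of 0.396 in spleen and 0.471 in lymph node, against at most 0.24 and 0.259 in 40 simulated mixtures. Called on the same side of both others were 5 and 34 genes (0 to 3 and 0 to 6 simulated). The shares agreed between the tissues (Spearman 0.606, bootstrap interval 0.535 to 0.67, 455 genes, highest of 2000 shuffles 0.168). Follicular TR among Id3+ eTR stay open, since Pdcd1, Tox2 and Cxcr5 stood above Id3+ cTR in lymph node while the follicular list was not below Id3+ eTR in Id3- eTR with an estimated correlation (adjusted p = 0.221), and the sort had no gate for or against them. A stage of its own, as the series title has it, may explain the values as well and was not tested apart from these.

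Hemoglobin and dissociation stress genes were higher in spleen. RNA of red cells carried into the sorts may explain the hemoglobin: the share of beta genes was steady (71.0%, SD 3.01 percentage points over 7 libraries), and the gates on CD4 and Foxp3 would remove red cells but not free RNA. It is argued against for the stress genes, since the 3 spleen libraries with under 10 CPM of hemoglobin had an excess of 0.517 to 0.565 on the log2 scale (SD of all excesses 0.151). That test replaced a first one whose result left the matter open, in which the excess in Id3+ cTR minus that in Id3- eTR was -0.137 ± 0.183 (SD, n = 3 mice). Preparation of the spleens and the tissue itself cannot be told apart for the stress genes, higher in spleen in 9 of 9 pairs, because every spleen library shares both.

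For comparisons of 3 libraries with 3, the 10 possible splits are too few for a share under 0.05. For genes in spleen, the real counts were 1526, 538 and 408 (Id3- eTR and Id3+ eTR against Id3+ cTR, then Id3- eTR against Id3+ eTR), and the highest other split gave 1 each time. In lymph node they were 1610, 705 and 326, with 0 in edgeR. Between the tissues they were 38, 36 and 1 in Id3- eTR, Id3+ eTR and Id3+ cTR, with 0, 0 and 1. Only the real split gave as many genes (2 in Id3+ cTR). Among the 4 splits that part all 3 mouse pairs, the highest other was 0, 1 and 1 in spleen and 0 elsewhere.

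For lists, the real counts in the same order were 16, 10 and 10 in spleen, 14, 14 and 9 in lymph node, and 8, 10 and 4 between the tissues. The highest other splits gave 13, 9, 11, 12, 9, 9, 4, 10 and 3, and the splits with as many, the real one included, numbered 1, 1, 2, 1, 1, 3, 1, 2 and 1. With an estimated correlation the real counts were 6, 7, 6, 10, 11, 6, 5, 4 and 0, and the highest others 1, 0, 1, 0, 0, 0, 0, 1 and 1. List counts at the preset correlation are therefore weak evidence, and low counts in other splits do not favour the estimated one. The list calls above state whether they held with it.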
